A study of Mus musculus with 2 samples.

How the data were processed

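The data are 2 MeDIP-seq libraries of epididymal white adipose tissue of male C57BL/6J mice, 1 from mice on regular chow (STD) and 1 from mice on a high-fat diet (HFD). Groups were taken from the diet named in the labels. Per the labels' protocols, genomic DNA was purified with a column kit and sequencing libraries were made by a sequencing centre. Per the submitters' processing notes, BWA, a read aligner, was used and the genome build was mm9. The peak caller, its threshold, read filters, the use of an input control and any pooling of mice are not given in the sources used here.

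The authors deposited 1 peak list per library, as BED files with 4 columns (chromosome, start, end and peak name). The deposited start and end positions are the only measurements, and there is no score, height, fold or p-value, so peaks were called per library and only their presence, position and width can be compared. Peak numbers in the names run without gaps from 1 to the end of each list, and no peaks of 1 list overlap. The smallest gap between neighbouring peaks was 50 bp in both lists. The narrowest width was 263 bp (STD) and 255 bp (HFD), shared by 11463 and 12515 peaks. A minimum that differs between lists shifts all widths, so widths were also expressed above the minimum of their own list. Sequencing depth is unknown. A deeper or more enriched library passes a caller's threshold at more weak sites, which can change peak number with no change in methylation.

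Positions are printed counting from 1. On 10 of 21 chromosomes a peak lay beyond the last gene of the gene table used here, which by itself does not show a mismatch of builds. That table follows a later mouse build than the mm9 of the peak lists. It was therefore not used to place peaks, and coordinates were not converted. Comparisons by gene and promoter, and the 15 gene lists (377 genes of adipocyte function, Hox clusters, inflammation, matrix, insulin signalling, imprinting, cell type markers and others) fixed before the data were examined, were left out for this reason. The design was kept as written otherwise. Where a score was to rank peaks, width was used.

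Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Peaks on chromosomes 1 to 19, X and Y were analysed, and 6 mitochondrial peaks per library were set aside. A peak had a partner when it overlapped a peak of the other list by at least 1 bp. The numbers with a partner were checked against bedtools 2.31.1 and were identical. Expected overlap came from 100 random placements of each list on the same chromosome, between its first and last peak, and from 100 placements within the same window of 1 Mb. Chromosome lengths were not used, and densities refer to the span from the first to the last peak. Windows of 1 Mb were filled by peak midpoint. Their dispersion is the mean squared deviation of the HFD share of peaks without a partner in units of its binomial variance, over windows with at least 20 such peaks, set beside 100 random assignments. Neighbouring peaks without a partner were compared with 100 shuffles of the library labels within chromosomes (1000 for the distances of 6 to 1000 kb together).

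Intervals are exact 95% binomial (Clopper-Pearson) intervals. They cover counting error only, and treat peaks as independent. With 1 library per diet no test across samples was possible, and leaving out a replicate was not possible either. The regions named in the report are, by a rule set before the data were examined, the 10 widest peaks without a partner in each list, the clearest of which are given in full, and the 5 windows of 1 Mb with the largest excess in each direction. The dispersion over windows at every window size, the widest peaks of all, the densest windows and the comparison of neighbours were chosen after the data had been examined, and the pooled distance of 6 to 1000 kb after its steps had been seen. On simulated lists of 152000 loci with 70% shared, the scripts recovered 69.8% shared, a dispersion of 0.920 without structure and 1.99 with 5 biased windows per chromosome. With neighbours made alike, 70.9% of simulated neighbours 1 to 20 kb apart came from the same library, against 50.4% after shuffling.

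Alternatives set before the data were examined were other overlap rules (50% of the shorter peak, reciprocal 50%, within 500 bp), autosomes only, merging of peaks across gaps of up to 500 bp, and numbers of peaks in place of covered bases. Alternatives added after seeing the data were the wider 50% of each list, the same number of widest peaks in each list (133145), peaks of at least 300 bp, peaks over 200 bp above the minimum width, and windows of 100 kb and 5 Mb.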

Results

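DNA methylation was profiled in epididymal white adipose tissue, the visceral fat depot beside the testis, of male C57BL/6J mice. C57BL/6J is an inbred strain commonly used in studies of diet-induced obesity. The mice received either regular chow (STD) or a high-fat diet (HFD) with 60% of its energy from fat for 5 months, from 4 weeks of age. The assay was MeDIP-seq, in which fragments of genomic DNA that carry 5-methylcytosine are captured with an antibody and sequenced. Each diet is represented by 1 library. The labels do not say how many mice contributed to each library. No difference below therefore has a replicate check, and no p-value is given. Intervals are exact 95% binomial intervals and cover counting error only. The sequencing depth is unknown, because the deposited lists give the positions of peaks and no counts.

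The STD list held 166438 peaks and the HFD list 175773 peaks, of which 6 in each lay on the mitochondrial chromosome and were set aside. On chromosomes 1 to 19, X and Y this left 166432 STD peaks that covered 61.3 Mb and 175767 HFD peaks that covered 62.6 Mb of mm9. The HFD list was 1.06 times as long as the STD list (interval 1.049 to 1.063). Its covered length was 1.02 times that of the STD list, as its peaks were narrower, with a median width of 321 bp against 332 bp. The narrowest peak was 255 bp in the HFD list and 263 bp in the STD list, and 12515 HFD peaks and 11463 STD peaks had exactly that width.

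The study's title names Hoxa5, a homeobox transcription factor gene of the Hoxa cluster on chromosome 6, and its methylation under high-fat feeding. The lists carry no gene names, and the gene table used here follows another genome build, so no peak was placed at Hoxa5 or at any other gene. For chromosome 6 as a whole, the STD list held 9093 peaks and the HFD list 9624. Of these, 72.6% of the STD peaks (71.7 to 73.5) and 68.7% of the HFD peaks (67.8 to 69.6) overlapped a peak of the other diet. HFD peaks made up 54.8% (53.4 to 56.1) of the chromosome 6 peaks found with 1 diet only, and the value over all chromosomes was 54.7%.

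The distribution of peaks over the genome was described first. Peaks were many and unevenly spread on the autosomes in both libraries, and few on chromosome X. Peak density was not adjusted for the number of sites that can be methylated or for how well reads map. It is therefore not a level of methylation, and a stretch without a peak is not thereby unmethylated. Chromosome 19 had the highest density, with 84.6 STD and 88.6 HFD peaks per Mb of the span between its first and last peak. Chromosome 11 followed with 82.9 and 87.4 peaks per Mb. The lowest autosomal values were 57.9 STD peaks per Mb on chromosome 3 and 61.2 HFD peaks per Mb on chromosome 14. Chromosome X carried 1036 STD and 1044 HFD peaks, or 6.33 and 6.38 peaks per Mb. The autosomal median density was 10.9 times that of X in the STD library and 11.5 times in the HFD library. On chromosome Y, 70 STD and 69 HFD peaks fell within a span of 2.86 Mb, at 24.4 and 24.1 peaks per Mb. The Y peaks were broad, with median widths of 408.5 bp and 403 bp, whereas X peaks were narrow, at 315 bp and 305 bp.

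**Figure D1:**
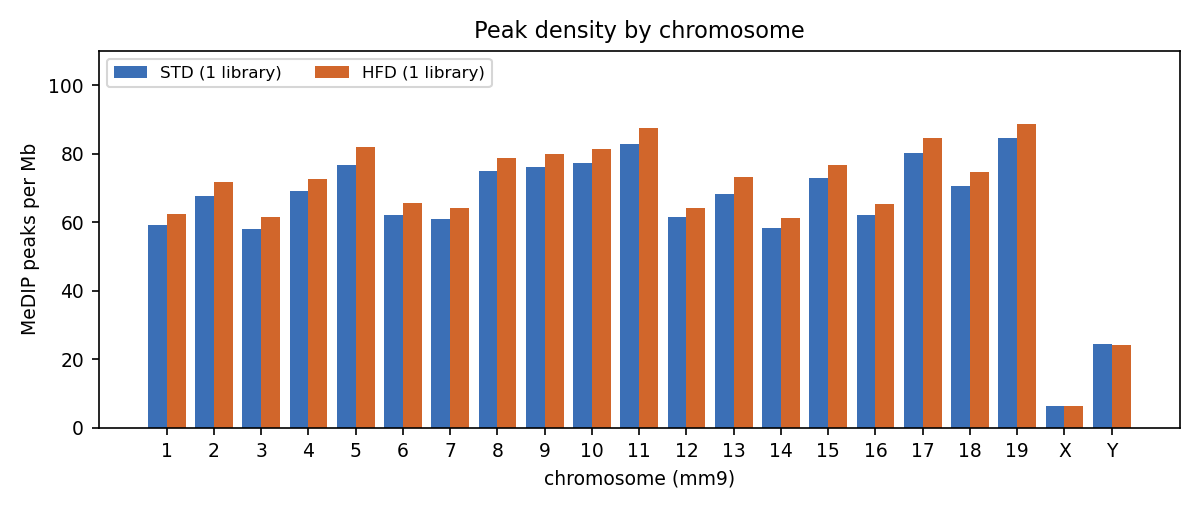
Bars give the number of MeDIP peaks per Mb of the span between the first and last peak of each mm9 chromosome, for 1 STD and 1 HFD library. The autosomes lie between 57.9 and 88.6 peaks per Mb and X lies near 6.3 in both libraries.

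Peak density rose toward the distal ends of the autosomes. In the first 10% of the span, which begins with the first peak, the density over 19 autosomes was 52.3 STD and 54.6 HFD peaks per Mb. In the last 10% it was 103 and 108 peaks per Mb, which is 1.97 and 1.98 times as high. The densest window of 1 Mb in both lists was 140 to 141 Mb on chromosome 4, with 199 STD and 198 HFD peaks. It was followed in both by 96 to 97 Mb on chromosome 15, with 192 and 196 peaks. Adjacent to it, the window from 97 to 98 Mb on chromosome 15 held 189 and 195 peaks. Across the 2573 windows with a peak, the numbers in the 2 libraries were correlated at r = 0.99. This correlation is across windows of the same pair of libraries, and windows are not independent replicates.

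**Figure D2:**
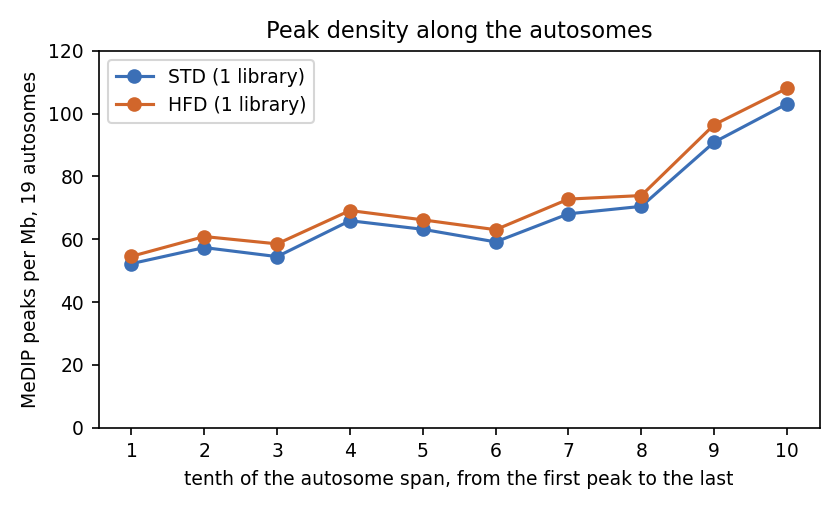
Points give the number of MeDIP peaks per Mb in each 10% of the span from the first to the last peak, summed over 19 autosomes, for 1 STD and 1 HFD library. Density in the last 10% is 103 (STD) and 108 (HFD) peaks per Mb, against 52.3 and 54.6 in the first 10%.

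The diets were then compared by asking which peaks had a partner, defined as a peak of the other list that overlapped it by at least 1 bp. Most peaks were found with both diets. Of the STD peaks, 122362 (73.5%, interval 73.3 to 73.7) had an HFD partner and 44070 had none. Of the HFD peaks, 122593 (69.7%, interval 69.53 to 69.96) had an STD partner and 53174 had none. Random placement of the peaks on their own chromosome gave on average 5.24% and 4.96%. Placement within the same window of 1 Mb, which keeps the regional density, gave 7.27% and 6.88%, so the observed shares were 10.1 times as high in both lists. Taken as 218985 separate loci, 55.6% were covered in both libraries, 24.3% with HFD only and 20.1% with STD only. In covered bases, 41.5 Mb were common to both lists out of 82.4 Mb in either, a Jaccard index of 0.503.

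Shared regions had nearly the same position and extent. Among the 120322 peaks with exactly 1 partner on each side, midpoints lay a median of 24 bp apart. HFD peaks differed from their STD partner by a median of -8 bp in width (quartiles -49 and 32 bp). The narrowest peaks of the lists differ by the same -8 bp. The broadest peaks were shared. All 20 of the peaks that are among the 10 widest of either list had a partner. Many of these are partners of each other, so they are fewer than 20 separate regions. The widest STD peak, on chromosome 15 from 85860877 to 85863111, was 2235 bp wide and its HFD partner 2292 bp. On chromosome 1, the STD peak from 69423073 to 69425082 was 2010 bp wide and its partner 1923 bp. On chromosome 8, the STD peak from 73436997 to 73438777 was 1781 bp wide and its partner 1865 bp. The widest HFD peak, on chromosome 17 from 39979959 to 39982558, spanned 2600 bp and overlapped 3 STD peaks of 1209, 298 and 510 bp.

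The share of peaks with a partner rose with peak width in both libraries. Width was used because the lists hold no score. It was measured from the narrowest peak of the same list, since that minimum differed between lists. Among peaks up to 20 bp above the minimum, 47.5% of the STD peaks and 42.8% of the HFD peaks had a partner. Among peaks over 200 bp above it, 93.7% and 92.8% had one. Peaks with a partner had a median width of 354 bp in the STD list and 345 bp in the HFD list. Peaks without one had a median width of 290 bp and 281 bp.

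The greater number of HFD peaks lay among peaks up to 100 bp above the minimum width, and was not limited to the narrowest. Up to 20 bp above the minimum width there were 40430 HFD and 36464 STD peaks, a ratio of 1.11 (1.09 to 1.12). At 21 to 50 bp the ratio was 1.09 (1.07 to 1.11), and at 51 to 100 bp it was 1.06 (1.04 to 1.07). Over 200 bp above it there were 24232 and 24272, a ratio of 0.998 (0.981 to 1.02). When only peaks of at least 300 bp were kept in both lists, the ratio was 0.958, so its direction depended on how narrow peaks were treated. Peaks over 200 bp above the minimum that were found with 1 diet only numbered 1751 for HFD and 1529 for STD, a ratio of 1.15 (1.07 to 1.23). The longer HFD list offered broad STD peaks more possible partners, and this ratio was not adjusted for that.

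**Figure D3:**
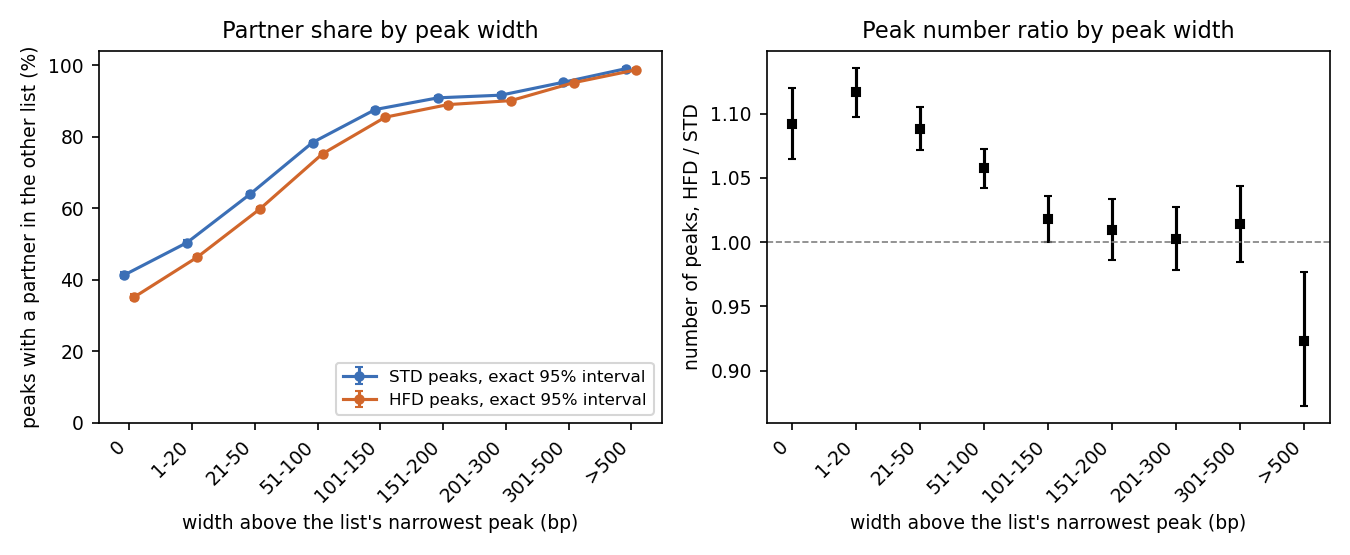
The left plot gives the percentage of peaks with a partner in the other list, and the right plot the HFD over STD ratio of peak number, by width in bp above the narrowest peak of each list, with exact 95% intervals for counting error. The partner share reaches 99.0% (STD) and 98.7% (HFD) for peaks over 500 bp above the minimum, and the ratio falls from 1.12 at 1 to 20 bp to 0.923 over 500 bp.

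The broadest peaks found with 1 diet only were listed by position. With STD, the broadest was on chromosome 4 from 140838429 to 140839562, with a width of 1134 bp, and the nearest HFD peak was 5.58 kb away. It was followed by chromosome 2 from 167641319 to 167642345 (1027 bp), where an HFD peak lay 1.15 kb away. Next came chromosome 1 from 33523570 to 33524506 (937 bp), with an HFD peak at 2.43 kb. On chromosome 10, the STD peak from 89360738 to 89361627 (890 bp) was 65.8 kb from any HFD peak. With HFD, the broadest was on chromosome X from 73211300 to 73212361, with a width of 1062 bp and no STD peak within 68.9 kb. Such a distance is not unusual on X, which held only 6.33 STD peaks per Mb. On chromosome 18, the HFD peak from 70581498 to 70582462 (965 bp) was 3.798 kb from an STD peak. On chromosome 2, the HFD peak from 113918659 to 113919602 (944 bp) was 6.80 kb from one. The 10 broadest of each list ranged from 846 to 1134 bp with STD and from 888 to 1062 bp with HFD. A peak of the other list lay within 500 bp of 1 of the 10 STD peaks and 4 of the 10 HFD peaks. One of these, on chromosome 2 from 174153347 to 174154246, had an STD peak of 822 bp at a distance of 0.101 kb.

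Whether peaks found with 1 diet only gathered in particular regions was examined in windows of 1 Mb. The largest excess of HFD peaks was on chromosome 3 from 143 to 144 Mb, with 41 HFD-only and 10 STD-only peaks. It was followed by chromosome 5 from 133 to 134 Mb, with 37 and 10, and by chromosome 6 from 113 to 114 Mb, with 47 and 20. On chromosome 17 from 12 to 13 Mb there were 51 and 26, and on chromosome 11 from 84 to 85 Mb 42 and 18. In the other direction, chromosome 3 from 131 to 132 Mb held 30 STD-only and 14 HFD-only peaks, and chromosome 17 from 46 to 47 Mb held 43 and 28. On chromosome 14 the windows from 25 to 26 Mb and from 64 to 65 Mb held 32 and 18, and 31 and 17. The window from 64 to 65 Mb on chromosome 13 held 29 and 16. None of these windows exceeded what chance gave among so many. When each such peak was assigned to a diet at random, the largest HFD excess in 100 draws ranged from 28 to 39 peaks, against 31 observed. The largest STD excess ranged from 15 to 28 in those draws, against 16 observed.

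**Figure D4:**
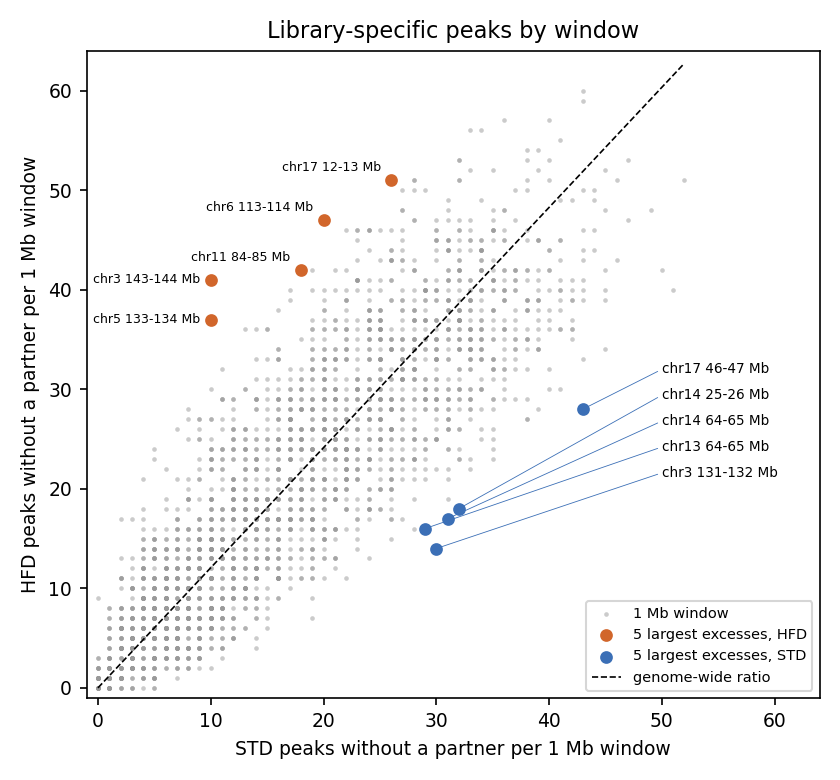
Each point is a window of 1 Mb, with its number of STD peaks without a partner (x axis) and of HFD peaks without a partner (y axis); the dashed line is the genome-wide ratio of 1.21. Named points are the 5 windows with the largest excess in each direction, and the largest HFD excess is 31 peaks on chromosome 3.

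Over the 1807 windows with at least 20 such peaks, the variance of the HFD share was 1.047 times that of binomial sampling. Random assignment gave between 0.904 and 1.08. This depended on window size: the value was just above the random range in windows of 5 Mb (1.131, random highest 1.127) and below it in windows of 100 kb (0.948, random lowest 0.974). By chromosome, the HFD share of peaks found with 1 diet only was highest on chromosome 13, at 56.4% (54.9 to 57.8), and on chromosome 5, at 55.9% (54.7 to 57.1). It was lowest on chromosome X among the chromosomes with more than 100 such peaks, at 50.3% (47.0 to 53.7). These 3 of the 21 chromosomes had intervals that left out the genome-wide 54.7%. Among 21 intervals at 95% some may do so by chance, and they treat neighbouring peaks as independent. Relative to the genome-wide ratio, the covered length of HFD over STD was 1.02 on chromosome 13 and 0.959 on X, and autosomes ranged from 0.993 to 1.02. On X, 57.9% of the STD peaks (54.8 to 60.9) and 57.7% of the HFD peaks (54.6 to 60.7) had a partner. Every autosome had at least 72.1% and 68.3%. On Y the shares were 85.7% (75.3 to 92.9) and 85.5% (74.96 to 92.8).

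Neighbouring peaks without a partner were then compared by distance. For neighbours 0.5 to 4.5 kb apart, 42.3% of 18150 came from the same library. In each step of distance within that range the share was below the lowest of 100 shuffles of the library labels. Between 1 and 2 kb, for example, it was 41.9%, and the shuffles ranged from 48.5% to 52.4%. From 4.5 kb onward the share was within the shuffled range in every step, with 50.7% at 6 to 8 kb and 51.1% at 20 to 50 kb, against shuffled means of 50.4% and 50.5%. Over all 70201 neighbours 6 to 1000 kb apart it was 51.06%, a small excess over the shuffled mean of 50.44% that was above the highest of 1000 shuffles (51.03%). The 2 libraries thus alternated between close neighbours more often than random labels did. With 1 library per diet this alternation cannot be assigned to diet.

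**Figure D5:**
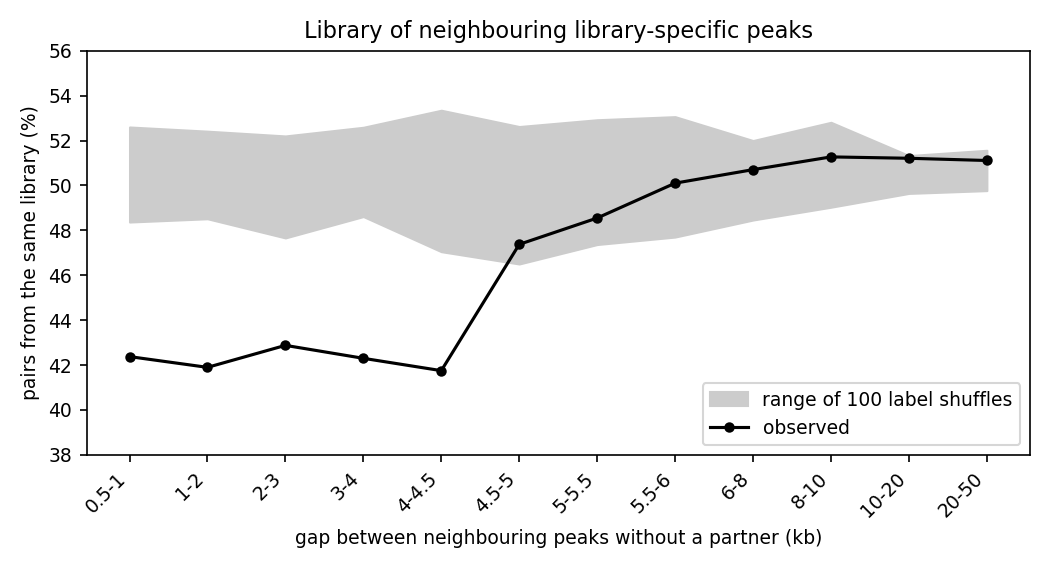
Points give the percentage of neighbouring peaks without a partner that came from the same library, by the gap between them in kb (steps of unequal size), and the grey band is the range of 100 shuffles of the library labels within chromosomes. The share stays near 42% up to 4.5 kb and lies within the band at longer gaps, in its upper part from 6 kb.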

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

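Both lists held 6 peaks on the mitochondrial chromosome, which the comparisons of the report did not use; this number was looked at because it exceeds the limit of 3 that a count of 0 allows, with no control library to set it against. The STD peaks covered 4049 bp and the HFD peaks 5004 bp of that chromosome, 3812 bp of it in both lists. Their median width was 484 bp in the STD list and 846.5 bp in the HFD list, against 332 bp and 321 bp for nuclear peaks, and the narrowest HFD peak among them, at 299 bp, was below the nuclear median. Read depth on this chromosome, which is present in many copies per cell, is not given in the lists.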

How the results depend on the processing

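The HFD over STD ratio of peak number, 1.06, reversed to 0.958 (0.9496 to 0.9656) for peaks of at least 300 bp. For peaks over 200 bp above the minimum width it was 0.998 (0.981 to 1.02), which shows no direction. The 300 bp filter removes more HFD peaks, whose minimum width is smaller. More HFD than STD peaks also lay up to 20 bp above their own minimum (40430 against 36464), and the 2 contributions were not separated. The share of peaks with a partner was 73.1% (STD) and 69.3% (HFD) with 50% of the shorter peak overlapping, 70.8% and 67.1% with reciprocal 50%, and 76.2% and 72.6% when a peak within 500 bp counted. Keeping the wider 50% of each list gave 68.7% and 65.2%, and the same number of widest peaks 70.4% and 70.5%, where a partner also had to pass the width limit. The Jaccard index was 0.5028 after merging gaps of up to 500 bp, 0.462 in the wider 50% and 0.494 with equal numbers. Autosomes only moved none of the values it was tried on beyond counting error. The HFD over STD ratio of covered bases on X relative to the genome, 0.959, stayed at 0.954 to 0.970, and peaks with a partner stayed wider at the median, by 53 bp (STD) and 54 bp (HFD) in the wider 50% against 64 bp in either full list. Of 25 recomputed values, the 10 of the share with a partner other than autosomes only moved beyond counting error. The 2 ratios of peak number for wider peaks, 0.958 and 0.998, did so too. For the Jaccard index no counting error was available. The dispersion over windows lay inside the random range at 1 Mb only (0.948 at 100 kb, 1.131 at 5 Mb). Of 28 alternatives planned before the data were examined, 8 needed a score that the lists lack and 12 needed gene positions on mm9, and these were not run. No paired analysis was possible because each diet has 1 library, and no replicate could be left out. Unknown depth limits every statement about the absence of a peak.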

Other observations

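Some stretches carried no peak at all. Within the spans of the autosomes and X, 19 windows of 1 Mb had no peak in either library, 13 of them on autosomes and 6 on X. On X, the fullest window, from 11 to 12 Mb, held 38 STD and 37 HFD peaks, and that from 7 to 8 Mb held 34 and 40. No X window held more peaks than the autosomal median of 128.5, counted over both lists. Runs of consecutive loci found with 1 diet only were no longer than in shuffled loci. The shuffles did not keep the alternation of close neighbours, which shortens runs, so this comparison cannot exclude stretches of 1 diet. The longest HFD-only runs had 8 loci, for example on chromosome 4 from 38014696 to 38195727 and on chromosome 6 from 55700014 to 55886038, and shuffled loci gave runs of up to 12. The longest STD-only run had 8 loci, on chromosome 14 from 18590694 to 18837992, against up to 10 after shuffling. Runs of at least 5 STD-only loci numbered 44, just under the 45 to 79 seen in shuffles, and those of HFD-only loci numbered 131, within 108 to 171.

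Of the tests below, the same-library share at 1 to 20 kb and the match of chromosome X to autosomal windows were set before their values were seen, although the share of X peaks with a partner was already known; the other tests were chosen after the values had been seen. The HFD list was longer than the STD list. A difference in depth or calling sensitivity may account for it: such a difference is expected to add mostly peaks near the threshold, and the ratio was 0.998 (0.981 to 1.02) for peaks over 200 bp above the minimum width. Over 500 bp above the minimum the ratio was 0.923 (0.872 to 0.977). Of the peaks over 200 bp above the minimum, 1751 HFD and 1529 STD peaks had no partner, a ratio of 1.15 (1.07 to 1.23). This concerns partners and not the number of broad peaks, and the longer HFD list offered broad STD peaks more possible partners. A diet effect at weakly enriched sites predicts the same excess of narrow peaks, for which the ratio was 1.11, and with 1 library per diet the explanations cannot be told apart.

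Peaks without a partner made up 26.5% of the STD list and 30.3% of the HFD list. A candidate explanation for many of them is chance at the calling threshold: from the narrow to the broad group of STD peaks the share with a partner rose by 46.2 percentage points. Whether diet-dependent stretches with several neighbouring peaks contribute is open: 48.4% of neighbours 1 to 20 kb apart came from the same library, below the shuffled range of 50.0% to 50.9%, but the closest neighbours lower that value, and at 6 to 1000 kb the share was 51.06%, above the highest of 1000 shuffles (51.03%). That excess over the shuffled mean was only 0.62 percentage points, and with 1 library per diet such stretches and regional differences in coverage between the libraries cannot be told apart. The deficit of same-library pairs, 8.60 percentage points at 1 to 2 kb, ended near 5 kb. A local background computed from a window of fixed size around each peak may cause it, since a peak then raises the bar for its neighbours in the same library. However, the peaks compared were narrow (median 290 bp with STD and 281 bp with HFD), and the strength of neighbours was not examined. The caller and its settings are not given in the sources used here.

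Chromosome X had a far lower peak density than the autosomes, by 10.9 times with STD and 11.5 times with HFD. Lower read coverage of the single X of males may contribute. The Y of males is also single and had 24.4 (STD) and 24.1 (HFD) peaks per Mb. Its peaks were broad, with median widths of 408.5 bp (STD) and 403 bp (HFD). Read coverage of Y is not known, so Y does not weigh for or against coverage as an explanation for X. Of its 70 STD and 69 HFD peaks, 85.7% and 85.5% had a partner, over a short span of 2.86 Mb. In the 127 of 158 X windows whose peak number also occurred in an autosomal window, 58.5% of 1815 peaks had a partner (56.2 to 60.7). These peaks pool both lists, so a shared region is counted from each list and the interval is too narrow. In those autosomal windows, weighted to the same peak numbers, the share was 62.5% (60.9 to 64.2 over 1000 resamplings of windows). The margin is small, and the windows were not matched on peak width. Median widths on X were 315 bp (STD) and 305 bp (HFD), against 332 bp and 321 bp for the median autosome. Narrow peaks had fewer partners in both lists. Coverage and sequence could both give narrow peaks on X, so the match cannot decide between them. How much of the low density is due to coverage and how much to sequence is open. Biological differences in methylation of X were not tested.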
